A study of Mus musculus with 6 samples.

How the data were processed

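RNA was measured in 6 libraries of PDGFRa+ cells, a fibroblast-enriched fraction sorted by flow cytometry from collagenase-digested mouse heart scar. All 6 came from hearts taken 7 days after injury, and all mice ate tamoxifen chow from 1 week before the injury onward. Libraries were made from total RNA with a directional kit, per the labels' protocols. The genotype label set the groups. The 4 Htr2b_cKO libraries carried loxP-flanked Htr2b with a tamoxifen-inducible Cre at 1 allele of Postn, and the 2 control libraries carried the loxP-flanked Htr2b alone. Replicates of the Htr2b_cKO group were numbered 1 to 4 and those of the control group 1 to 2. The series design speaks of animals, and each library was taken as 1 animal.

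The deposited estimated counts are whole numbers per Ensembl gene that are not normalized. Their column names, per the file headers, end as gene-level output of a transcript quantifier does, so the deposited estimated counts were taken as rounded estimates. They were used as they stand. The authors also deposited a normalized signal, in which each estimated count is divided by a factor of that gene and library. For the 11930 genes with a mean count of 100 or more, the geometric mean of these factors over the 6 libraries lay within 0.1% of 1 for each gene. The SD over genes of the log2 factor was 0.128 to 0.193 per library, so the authors' normalized signal is not scaled by 1 factor per library. DRAGEN, DESeq2 and the mouse build mm10 are named, without versions or roles, per the submitters' processing notes. The counter's settings, including strand and the gene annotation, are not given in the sources used here. Gene symbols, coordinates, exon lengths and GC content came from a GENCODE annotation of the same build, in which all 42256 gene identifiers of the table were found. Counts per gene cannot show whether a floxed exon was removed.

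Library totals ran from 28533427 to 37392496 estimated counts. A count of 0 allows up to 3 counts, which is 0.078 to 0.108 CPM per library. This floor covers counting error only. All 15 pairs of libraries differed far beyond sampling noise, with a chi-square per degree of freedom of 50.4 to 206 over genes, so no library was a copy of another.

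The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with genotype as its only term. Library sizes were scaled by TMM, low counts were removed with filterByExpr, and dispersions were fitted robustly. This left 15840 of 42256 genes. Benjamini-Hochberg adjusted p under 0.05 was a call. Log2 fold changes are Htr2b_cKO minus control, and each SE is the size of the fold change divided by the square root of F. CPM values use TMM-scaled library sizes and are given as mean ± SD. With 2 against 4 libraries there are 15 splits, and the smallest p that a permutation test could give is 0.0667, so no permutation test of a single gene could reach 0.05.

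The design, the tests, 30 gene lists and the rule for named genes were set before the data were examined. There were 18 program lists, 10 lists of cell type markers and 2 lists of sex-linked genes. The program lists were myofibroblast contractile genes, extracellular matrix, collagen crosslinking and processing, matrix proteases and inhibitors, TGF-β signalling and targets, cell cycle, resting fibroblast, matrifibrocyte and chondrogenic genes, inflammatory mediators, interferon response, serotonin receptors and handling, Gq, Src and MAPK signalling, immediate early and dissociation genes, hypoxia and glycolysis, oxidative phosphorylation, YAP targets, integrin and focal adhesion, and unfolded protein and secretion. The marker lists were cardiomyocyte, endothelial, mural, macrophage, neutrophil, lymphocyte, Schwann, epicardial and mesothelial, erythroid, and adipocyte. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 27 lists that had at least 3 tested members. Camera compares the genes of a list with all other genes. The same lists were tested with an estimated correlation and with fry, whose directional p tests whether a list moves one way on balance and whose mixed p tests for change in either direction. Members were also adjusted over the list alone.

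Named genes were Htr2b and Postn; per direction up to 10 called genes with the largest fold change, mean log2 CPM of at least 1 and groups that did not overlap, leaving out predicted models and pseudogenes; where fewer than 5 met this, the 5 with the smallest p in that direction; up to 4 called members of each program list, or the 2 with the smallest p; the 2 most abundant members of each marker list; and the sex-linked genes. Some genes that the rule took are not described in the text. No gene met the second part, so the smallest-p genes were named. Ighv4-1 entered that way, because it passed the test but its mean log2 CPM of 0.71 was under the minimum. Rps3a1, Rps3a2, Rps3a3, Tpm3, Ighm, Igkc, Jchain, Mzb1, Pou2af1, the collagens Col1a1, Col1a2 and Col3a1, further members of lists with unadjusted p under 0.05, and the copies and genes of chromosome 3 named in the closing section were chosen after their values were seen.

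The alternatives set beforehand were RLE and upper-quartile scaling, no filter, a filter of CPM of at least 1 in 2 libraries, and DESeq2 1.42.0. They also included limma voom, 2 other dispersion settings, leaving out each library, and sex as a covariate. Only 1 library was male, so the sex term takes up that library and the fit stands close to leaving it out. Of the alternatives chosen after seeing the data, 1 used the authors' gene-specific factors as offsets and 1 corrected each library for a smooth trend in GC content and exon length. Another left out the libraries labelled Htr2b_cKO 3 and Htr2b_cKO 4, and the last added the mean macrophage marker level as a covariate. The GC and length trend was fitted with splines of 5 degrees of freedom on 12669 genes, and 15825 of the 15840 tested genes had a GC value. Near-identical copies were sought with blastn 2.17.0 between 690 expressed pseudogenes or named copies and protein-coding transcripts, at 90% identity over 50% of the length or more, and 623 had such a parent.

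The tests were tested on simulated data made from the real means, library sizes and dispersions of Htr2b_cKO against control. In these data 200 genes were changed by a log2 fold of 1 or 2, and 30 others, the shifted list, by less. Over 15513 genes edgeR called 30% of genes changed by a log2 fold of 1 and 80% of those changed by a log2 fold of 2, with 14 unchanged genes called. Over 15840 genes DESeq2 called 52% and 90%, with 52 unchanged genes called. Limma voom over 15513 genes called 28% and 79%, with 5 unchanged genes called. Camera, without adjustment, gave 4.18e-10 for a shifted list and 0.301 for an unchanged one. The simulated genes were drawn independently, so this does not test camera on lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.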

Results

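Expression was profiled in PDGFRa+ cells sorted from the infarct scar of mice on a mixed 129S2/C57Bl6 background, 7 days after injury. PDGFRa is a surface receptor that marks cardiac fibroblasts. In 4 libraries the mice were Htr2b_cKO, with Htr2b floxed and a tamoxifen-inducible Cre carried at the locus of Postn, the periostin gene that activated fibroblasts switch on. In the 2 control libraries Htr2b was floxed and no Cre was carried. The comparison asks how loss of the serotonin receptor gene Htr2b from myofibroblasts alters the transcriptome of scar fibroblasts. Because no control carried the Cre, effects of the Cre and of its Postn allele cannot be told apart from loss of Htr2b. The control libraries held 37392496 and 28565473 estimated counts. The Htr2b_cKO libraries held 28533427, 33128098, 31481527 and 34830718. The pair of control libraries limits every comparison that follows. The library labelled Htr2b_cKO 4 had 0.267 CPM of Xist and 139 CPM over the Y-linked genes, and it was the only male; in the other 5 libraries Xist was at 385 CPM or more and the Y-linked sum at 0.483 CPM or less. Kdm5d, the only Y-linked gene of the list to pass the filter, was at 0 in both control libraries and at 26.6 CPM in the library labelled Htr2b_cKO 4.

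Htr2b itself was barely detected in any library. The control libraries had 13 and 7 estimated counts, which are 0.338 and 0.253 CPM. Of the Htr2b_cKO libraries, the first had 0 counts, which allows up to 0.107 CPM, the second had 3 and the fourth had 4. The library labelled Htr2b_cKO 3 had 29 counts, or 0.876 CPM, above both controls, so the target gene did not bear out its label. Htr2b (ENSMUSG00000026228) spans chromosome 1 from 86099026 to 86111970 in mm10. Its log2 fold change was -0.11 (SE 1.18, edgeR adjusted p = 0.982), and 2 SEs on either side reach from -2.47 to 2.26. A loss of Htr2b was therefore not detectable, with so few counts and with the library labelled Htr2b_cKO 3 above both controls. Counts over the whole gene do not see the removal of an exon, and the Cre acts in the Postn lineage alone. The estimate turned positive without control 1 (0.14), Htr2b_cKO 1 (0.26), Htr2b_cKO 2 (0.20) or Htr2b_cKO 4 (0.16), and without the library labelled Htr2b_cKO 3 it was -1.97.

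Postn (ENSMUSG00000027750, chromosome 3 from 54361109 to 54391037) stood at 1947 ± 512 CPM in control and 1542 ± 561 CPM in Htr2b_cKO libraries. The difference (log2 fold change -0.34, SE 0.33, adjusted p = 0.774) was smaller than the spread between libraries; it was -0.04 without control 1 and -0.92 after the GC and length correction. Pdgfra, the gene of the sorting marker, was at 985 ± 357 CPM in control and 900 ± 204 CPM in Htr2b_cKO libraries, and the fibrillar collagen genes were among the most abundant transcripts. Col1a1 had 27717 ± 3159 CPM in control and 29298 ± 8463 CPM in Htr2b_cKO libraries, Col3a1 44188 ± 10053 and 47587 ± 9407 CPM, and Col1a2 24407 ± 2841 and 25677 ± 6182 CPM. None of these differed beyond the spread between libraries (adjusted p of 0.906 to 0.959 for Pdgfra, Col1a1, Col1a2 and Col3a1, all from the edgeR fit).

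**Figure D1:**
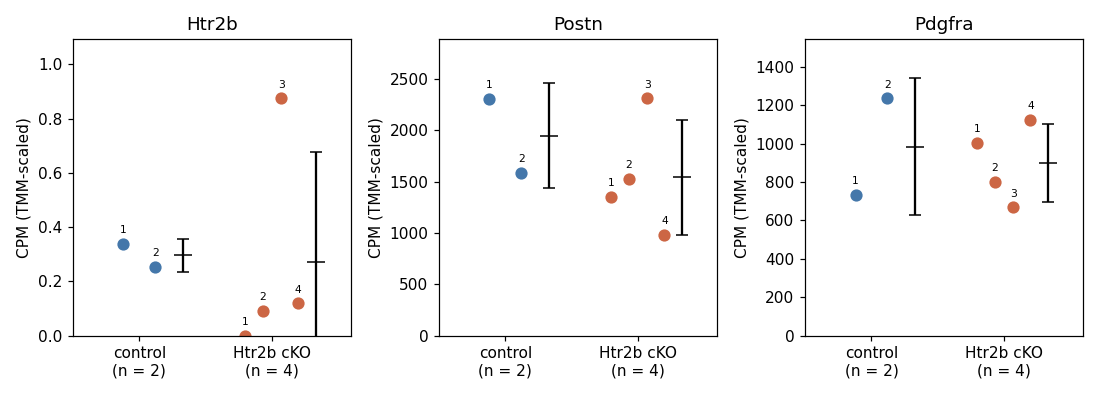
Htr2b, Postn and Pdgfra in each library, in CPM scaled by TMM, with replicate numbers beside the points and the group mean ± SD as bars (control n = 2, Htr2b cKO n = 4). Htr2b reached 0.876 CPM in the library labelled Htr2b_cKO 3, and the groups overlapped for all 3 genes.

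Of 15840 genes tested, 3 were called. The number was 1 without control 1, 6 without control 2 and 8 without the library labelled Htr2b_cKO 4. Both genes called higher in Htr2b_cKO were copies of Rps3a1, which encodes a protein of the small ribosomal subunit. Rps3a3 (ENSMUSG00000059751, a processed pseudogene on chromosome 13 from 108670603 to 108671397) stood at 0.327 ± 0.053 CPM in control and 104 ± 14 CPM in Htr2b_cKO libraries, 317-fold higher (log2 fold change 8.27, SE 0.28, adjusted p = 1.0e-05). Rps3a2 (ENSMUSG00000062611, a processed pseudogene on chromosome 14 from 88123017 to 88123808) rose 7.0-fold, from 40.4 ± 2.4 to 283 ± 37 CPM (log2 fold change 2.81, SE 0.18, adjusted p = 0.00124). Rps3a1 on chromosome 3, from 86137940 to 86142702, was at 946 ± 52 CPM in control and 571 ± 65 CPM in Htr2b_cKO libraries (log2 fold change -0.73, SE 0.16, adjusted p = 0.322). The copies match Rps3a1 at 98.9% and 99.5% of bases, so how the counting divided reads among them is uncertain. The 3 genes together gave 987 ± 50 CPM in control and 957 ± 113 CPM in Htr2b_cKO libraries. All 4 Htr2b_cKO libraries lay above both controls for Rps3a3 and Rps3a2, with the library labelled Htr2b_cKO 3 at 119 CPM of Rps3a3. Without control 1 Rps3a2 was no longer called (adjusted p = 0.0501), and limma voom did not call Rps3a3 (adjusted p = 0.0711).

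A second gene family showed the same arrangement without passing the test. Tpm3-rs7, a copy of the tropomyosin gene Tpm3 on chromosome 14, had 62.2 ± 1.6 CPM in control and 168 ± 23 CPM in Htr2b_cKO libraries (log2 fold change 1.43, SE 0.17, adjusted p = 0.0817). Tpm3 on chromosome 3, from 90072649 to 90100902, had 367 ± 7 CPM in control and 252 ± 29 CPM in Htr2b_cKO libraries (log2 fold change -0.54, SE 0.15, adjusted p = 0.372). The copy matches its parent at 99.1% of bases over 98.2% of its length. Tpm3-rs7 passed after the GC and length correction (adjusted p = 0.0277). The pair summed to 429 ± 9 CPM in control and 420 ± 52 CPM in Htr2b_cKO libraries.

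**Figure D2:**
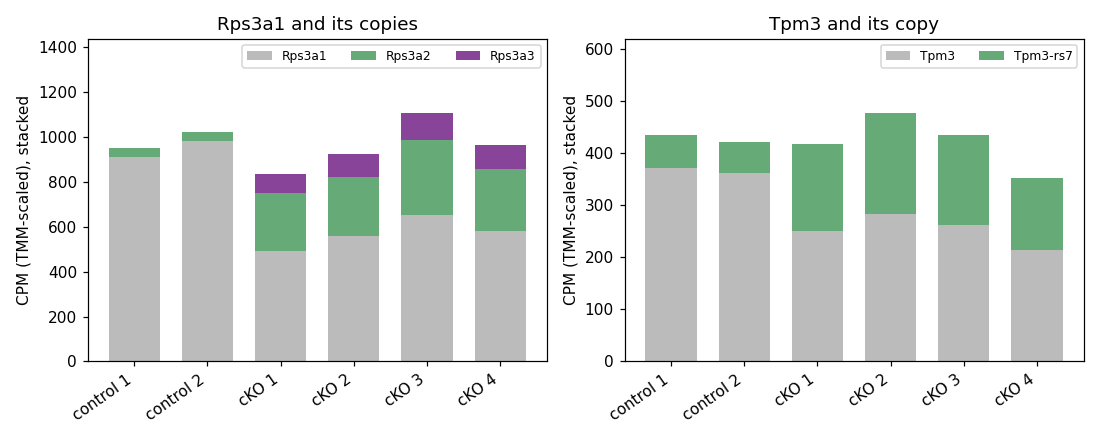
Stacked CPM of Rps3a1 and its copies Rps3a2 and Rps3a3 (left) and of Tpm3 and its copy Tpm3-rs7 (right), with 1 bar for each library. Rps3a3 stood at 84.9 to 119 CPM in the Htr2b cKO libraries and at 0.289 and 0.364 CPM in the control libraries, while the height of the whole Rps3a bar ran from 834 to 1106 CPM.

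The gene called lower was Ighv4-1 (ENSMUSG00000076655), a variable segment of the immunoglobulin heavy chain on chromosome 12 from 113948282 to 113948796. It had 4.58 ± 2.54 CPM in control and 0.038 ± 0.075 CPM in Htr2b_cKO libraries, where 3 of the 4 had 0 counts (log2 fold change -6.77, SE 0.83, adjusted p = 0.023). The call was lost without control 1 (adjusted p = 0.739), Htr2b_cKO 1 (0.0985), Htr2b_cKO 2 (0.118) or the library labelled Htr2b_cKO 3 (0.181), with DESeq2 (0.185), limma voom (0.351), the legacy dispersion (0.305) or the authors' factors (0.0653), and without both Htr2b_cKO 3 and Htr2b_cKO 4 (0.335). Other immunoglobulin segments among the smallest p were Ighv2-9-1, at 2.19 ± 0.59 against 0.030 ± 0.059 CPM, Ighv1-80, at 2.14 ± 1.67 against 0.060 ± 0.121 CPM, and Igkv12-41, at 1.15 ± 0.11 against 0.030 ± 0.059 CPM. Their adjusted p values were 0.107, 0.265 and 0.304 in the same edgeR fit.

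Immunoglobulin genes as a class had lower values in most Htr2b_cKO libraries. Of 113 tested, 99 had a log2 fold change below 0, 29 had an unadjusted p under 0.05 on the lower side and 0 on the higher side, and 1 was called. The heavy chain constant gene Ighm was at 1042 and 1038 CPM in the control libraries and at 156, 139, 263 and 879 CPM in the Htr2b_cKO libraries (log2 fold change -1.53, SE 0.79, adjusted p = 0.604). Without the library labelled Htr2b_cKO 4, Ighm was called lower (log2 fold change -2.48, adjusted p = 0.0414). The light chain gene Igkc stood at 346 ± 42 CPM in control and 121 ± 112 CPM in Htr2b_cKO libraries (adjusted p = 0.591). Jchain, which joins secreted immunoglobulin M and A, was at 127 ± 22 and 42.6 ± 39.3 CPM (adjusted p = 0.573). The B-cell gene Cd79a did not follow Ighm, with 7.78 and 2.24 CPM in the control libraries and 1.14, 0.783, 2.87 and 1.43 CPM in the Htr2b_cKO libraries.

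**Figure D3:**
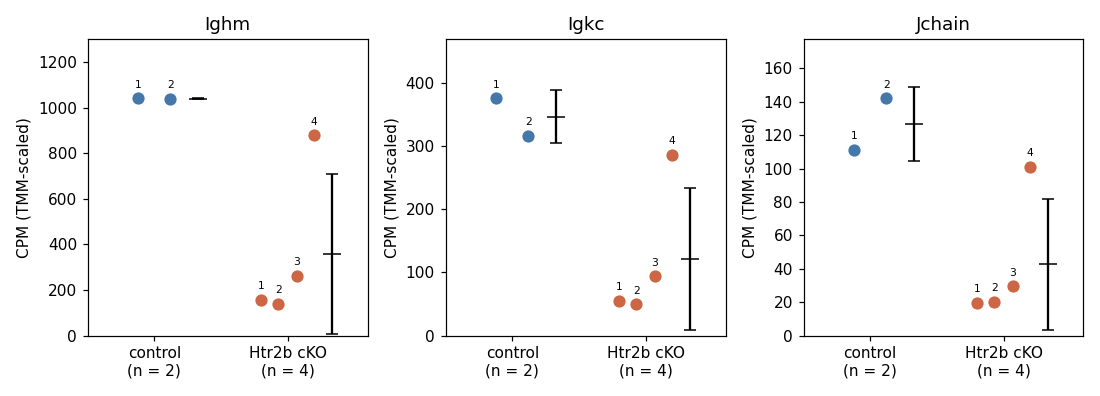
Ighm, Igkc and Jchain in each library, in CPM scaled by TMM, with replicate numbers beside the points and the group mean ± SD as bars (control n = 2, Htr2b cKO n = 4). The library labelled Htr2b_cKO 4 had 879 CPM of Ighm, near the 1042 and 1038 CPM of the control libraries, and the other Htr2b cKO libraries had 139 to 263 CPM.

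With the 3 calls included, 1519 genes had an unadjusted p under 0.05, of which 1046 were higher and 473 lower. Chance gives 792 on average, and genes that move together widen the spread around that number. Other splits of the 6 libraries gave 309 to 2498, and 2 of them exceeded 1519. The Htr2b_cKO libraries lay wholly above or below both controls for 19.6% of genes, and chance gives 13.3%. DESeq2 called 105 genes, 85 higher and 20 lower. Without control 1 the number with an unadjusted p under 0.05 was 541. After correction of each library for GC content and exon length it was 900, with 474 higher and 426 lower. Among the higher genes with the smallest p were Cenpf, a kinetochore protein, Smc5, part of a chromosome maintenance complex, and Arhgap5. Cenpf had 14.2 ± 1.9 CPM in control and 33.3 ± 4.2 CPM in Htr2b_cKO libraries (log2 fold change 1.23, SE 0.18, adjusted p = 0.21), Smc5 18.4 ± 0.1 and 34.1 ± 1.8 CPM, and Arhgap5 19.5 ± 0.4 and 39.97 ± 5.00 CPM. After the GC and length correction the log2 fold change of Cenpf was 0.86, that of Smc5 moved from 0.89 to 0.44, and that of Arhgap5 from 1.03 to 0.37. On the lower side H2-Q6, a nonclassical major histocompatibility gene whose close paralogs could share its reads, had 101 ± 3 CPM in control and 58.4 ± 6.9 CPM in Htr2b_cKO libraries (adjusted p = 0.304).

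Among the 27 gene lists tested with camera, 8 passed, 2 of them higher and 6 lower in Htr2b_cKO, and 5 passed without Htr2b_cKO 2. With an estimated inter-gene correlation 0 of the 27 passed, and with fry 0 passed in one direction. The adjusted p of 0.799 given below for the estimated correlation is shared by many lists, because the adjustment ties them. No list had a member called over all genes by edgeR, and 9 members were called when adjusted over the list alone. DESeq2 called list members over all genes, among them Cenpf, Skil, Cenpe, Mki67 and Ogn. Of 16 contractile myofibroblast genes, 7 were above 0 and 9 below, with a median log2 fold change of -0.01, and the list did not pass (camera adjusted p = 0.912). It passed on the higher side without control 1 (median 0.42, camera adjusted p = 0.00245) and on the lower side without control 2 (median -0.30, 0.00941). Acta2, the smooth muscle actin gene of myofibroblasts, had 342 ± 156 CPM in control and 263 ± 34 CPM in Htr2b_cKO libraries (adjusted p = 0.667), and its fold change turned positive without control 1 (0.18). Ccn4 had 57.9 ± 1.7 and 80.5 ± 24.9 CPM (adjusted p = 0.657).

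Genes of the extracellular matrix leaned higher without passing. Of 27 genes 20 were above 0, with a median of 0.13 (camera adjusted p = 0.107). The median was 0.09 without control 1 and 0.32 without control 2. The list passed on the higher side without the library labelled Htr2b_cKO 3 (median 0.25, camera adjusted p = 0.00174), without both Htr2b_cKO 3 and Htr2b_cKO 4 (0.000203), and after the GC and length correction (0.0471). The proteoglycan gene Vcan had 447 ± 130 CPM in control and 672 ± 146 CPM in Htr2b_cKO libraries (log2 fold change 0.59, adjusted p = 0.52; 0.32 without control 1, 0.93 without control 2, 0.28 after the GC and length correction), and Lum had 1025 ± 182 and 1362 ± 216 CPM (adjusted p = 0.589). For collagen crosslinking and processing 14 of 23 genes were above 0 (camera adjusted p = 0.546; 0.0105 after the GC and length correction, higher), with the lysyl oxidase family gene Loxl4 at 11.7 ± 0.2 and 19.6 ± 7.6 CPM and the prolyl hydroxylase subunit gene P4ha3 at 55.4 ± 13.1 and 70.3 ± 7.0 CPM. For matrix proteases and inhibitors 16 of 24 were above 0 (camera adjusted p = 0.909). The gelatinase gene Mmp9 had 41.3 ± 16.8 CPM in control and 23.9 ± 5.1 CPM in Htr2b_cKO libraries (log2 fold change -0.79; -0.30 without control 1), and the inhibitor gene Timp4 had 4.73 ± 5.56 and 0.947 ± 0.651 CPM. Resting fibroblast genes were divided 10 above and 8 below (camera adjusted p = 0.912), with Lpl at 278 ± 5 and 326 ± 27 CPM and Abca8a at 145 ± 34 and 202 ± 76 CPM. Of 18 tested matrifibrocyte and chondrogenic genes 12 were above 0 (camera adjusted p = 0.107), led by the matrix proteoglycan gene Ogn at 173 ± 34 and 352 ± 115 CPM (log2 fold change 1.03, SE 0.30, adjusted p = 0.401; 0.57 after the GC and length correction) and the bone transcription factor gene Runx2 at 7.56 ± 2.00 and 10.8 ± 1.5 CPM. That list passed on the higher side without Htr2b_cKO 1 (camera adjusted p = 0.0266) or Htr2b_cKO 4 (0.0331). It also passed with the macrophage score as a covariate (0.02) and after the GC and length correction (0.00173). The pass with sex as a covariate (0.0319) is not a separate check, because the sex term takes up Htr2b_cKO 4. Without control 1 the median of the list was 0.71.

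Genes of TGF-β signalling and its targets were higher as a group. Of 23 genes 18 were above 0, with a median log2 fold change of 0.26 (camera adjusted p = 0.0109). With its estimated correlation of -0.041 the list did not pass (camera p = 0.03, adjusted p = 0.799). The other lists that passed had an unadjusted camera p of 0.148 to 0.447 with their estimated correlations. Directional fry gave an adjusted p of 0.0809 for the TGF-β list, which did not pass there either. Skil, which encodes a repressor of SMAD transcription factors, had 57.5 ± 9.4 CPM in control and 110 ± 13 CPM in Htr2b_cKO libraries (log2 fold change 0.93, SE 0.17, adjusted p = 0.304 over all genes and 0.00908 adjusted over the list alone). The receptor gene Tgfbr1 had 62.8 ± 14.9 and 95.5 ± 10.2 CPM (adjusted p = 0.393 over all genes and 0.0944 adjusted over the list alone). After the GC and length correction the log2 fold change of Skil was 0.55 and that of Tgfbr1 moved from 0.61 to 0.28, and the list passed (camera adjusted p = 0.00173). The list did not pass without control 2 (camera adjusted p = 0.0711), and its median was 0.13 without both Htr2b_cKO 3 and Htr2b_cKO 4.

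The cell cycle list passed on the higher side, although its median was 0.02 and only 16 of its 31 genes were above 0 (camera adjusted p = 0.018; adjusted p = 0.799 with an estimated correlation). All 8 members with an unadjusted p under 0.05 were higher. Cenpf, Cenpe and Mki67 were called when adjusted over the list alone (adjusted p of 0.00287, 0.0129 and 0.0184). The kinetochore motor gene Cenpe had 15.3 ± 0.2 CPM in control and 32.6 ± 6.8 CPM in Htr2b_cKO libraries, and the proliferation marker Mki67 had 59.7 ± 3.5 and 107 ± 19 CPM. The median was 0.27 without control 1, and the list did not pass without control 2 (median -0.06, camera adjusted p = 0.907) or without Htr2b_cKO 2 (0.258), or with the authors' gene-specific factors as offsets (0.0531). It passed after the GC and length correction (0.00781). Genes of integrins and focal adhesions did not pass camera (21 of 33 above 0, adjusted p = 0.211) but did pass the mixed test of fry (adjusted p = 0.0355). Of its members 2 were called over the list alone, both higher. Camera passed on the higher side without the library labelled Htr2b_cKO 3 (adjusted p = 0.0282) and without both Htr2b_cKO 3 and Htr2b_cKO 4 (0.0376). YAP targets did not pass (15 of 21 above 0, camera adjusted p = 0.334), with Rbms3 at 41.1 ± 8.2 and 57.7 ± 9.3 CPM and Ankrd1 at 7.54 ± 2.73 and 5.19 ± 2.21 CPM.

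Genes of oxidative phosphorylation were lower as a group. Of 28 genes 26 were below 0, with a median log2 fold change of -0.21 (camera adjusted p = 0.00115; adjusted p = 0.799 with an estimated correlation). Uqcrc1 of complex III had 146 ± 13 CPM in control and 117 ± 10 CPM in Htr2b_cKO libraries (adjusted p = 0.511), and Ndufv1 of complex I had 93.2 ± 6.9 and 78.0 ± 3.2 CPM (adjusted p = 0.558). The list did not pass without control 1 (median -0.08, camera adjusted p = 0.0779), and it passed after the GC and length correction (0.00389) with a median of -0.09. Hypoxia and glycolysis genes did not pass (8 of 18 above 0, camera adjusted p = 0.912), with Vegfa at 116 ± 0.4 and 148 ± 35 CPM and Ankrd37 at 2.27 ± 1.02 and 1.57 ± 0.46 CPM. The unfolded protein and secretion list did not pass (13 of 19 above 0, camera adjusted p = 0.609), with the stress genes Herpud1 at 67.2 ± 2.6 and 55.6 ± 5.0 CPM and Xbp1 at 268 ± 26 and 216 ± 34 CPM.

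Interferon response genes were lower as a group. Of 22 genes 19 were below 0, with a median log2 fold change of -0.25 (camera adjusted p = 0.00247; adjusted p = 0.799 with an estimated correlation). The interferon transcription factor gene Irf7 had 331 ± 2 CPM in control and 218 ± 60 CPM in Htr2b_cKO libraries (log2 fold change -0.60, SE 0.22, adjusted p = 0.462). Oas1a, an antiviral sensor gene, had 75.0 ± 8.2 and 51.9 ± 14.1 CPM (adjusted p = 0.51). The list did not pass without Htr2b_cKO 2 (median -0.12, camera adjusted p = 0.14), and its median was -0.44 without the library labelled Htr2b_cKO 3 and -0.64 without both Htr2b_cKO 3 and Htr2b_cKO 4. Inflammatory mediators did not pass (11 of 26 above 0, camera adjusted p = 0.49), but passed on the lower side without control 1 (0.00245) and with the macrophage covariate (0.0274). The chemokine gene Cxcl10 had 71.1 ± 12.8 CPM in control and 55.8 ± 1.3 CPM in Htr2b_cKO libraries, and the prostaglandin synthase gene Ptgs2 had 177 ± 86 and 289 ± 85 CPM. Immediate early and dissociation genes did not pass (18 of 23 above 0, camera adjusted p = 0.219), but passed on the higher side after the GC and length correction (median 0.29, camera adjusted p = 0.000203) and without control 2 (0.00641), with Egr2 at 39.5 ± 8.4 and 57.0 ± 13.3 CPM and Fosb at 1264 ± 140 and 1821 ± 454 CPM.

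Only 6 of the 16 genes of serotonin receptors and handling passed the filter, and 3 of those were above 0 (camera adjusted p = 0.49). The serotonin transporter gene Slc6a4 had 20.2 ± 8.3 CPM in control and 12.4 ± 1.3 CPM in Htr2b_cKO libraries (log2 fold change -0.70, SE 0.24, adjusted p = 0.427; -1.08 without control 1 and -0.21 without control 2). Maoa, whose enzyme breaks down serotonin, had 23.7 ± 0.3 and 19.1 ± 3.3 CPM (adjusted p = 0.625). Without control 1 that list passed on the lower side (camera adjusted p = 0.0112). Genes of Gq, Src and MAPK signalling, through which the receptor can act, did not pass (12 of 18 above 0, camera adjusted p = 0.559). The Src family kinase gene Yes1 had 12.1 ± 2.1 CPM in control and 21.4 ± 3.4 CPM in Htr2b_cKO libraries (adjusted p = 0.337), and the phospholipase gene Plcb4 had 14.6 ± 3.4 and 23.5 ± 6.3 CPM (adjusted p = 0.488).

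Of the lists of other cell type markers, 4 passed camera on the lower side. Endothelial markers were below 0 for 12 of 13 genes, with a median of -0.92 (camera adjusted p = 0.00203; adjusted p = 0.799 with an estimated correlation). Endothelial transcripts made up 0.0412% of counts in control 1 and 0.0101% to 0.0196% in the other 5 libraries. Without control 1 the list passed in the opposite direction, with a median of 0.48 (camera adjusted p = 0.0112), and without control 2 the median was -1.49. Pecam1 had 36.5 ± 34.4 CPM in control and 17.1 ± 7.8 CPM in Htr2b_cKO libraries, and Tek had 34.1 ± 14.03 and 44.5 ± 22.5 CPM.

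Neutrophil markers were below 0 for 9 of 9 genes (camera adjusted p = 0.00704; adjusted p = 0.799 with an estimated correlation). The granule genes Ltf and Ngp were called over the list alone (adjusted p of 0.011 and 0.0457), with Ltf at 1.92 ± 2.25 CPM in control and 0.135 ± 0.093 CPM in Htr2b_cKO libraries. S100a9 had 31.0 ± 20.4 and 19.5 ± 15.2 CPM, and S100a8 21.8 ± 15.2 and 10.4 ± 8.7 CPM (log2 fold change -1.07; -0.07 without control 1 and -1.84 without Htr2b_cKO 4). The list did not pass without control 1 (median 0.22, camera adjusted p = 0.605), without Htr2b_cKO 2 (0.14) or with the filter of CPM of at least 1 in 2 libraries (0.147). Lymphocyte markers were below 0 for 8 of 9 tested genes, with a median of -1.35 (camera adjusted p = 0.00704; adjusted p = 0.799 with an estimated correlation), and did not pass without control 1 (median -0.13, camera adjusted p = 0.278). Cd4 had 2.31 ± 1.74 and 1.99 ± 1.88 CPM. Epicardial and mesothelial markers were below 0 for 8 of 8 tested genes (camera adjusted p = 0.0109; adjusted p = 0.799 with an estimated correlation), with Upk3b at 90.1 ± 11.7 and 55.2 ± 24.2 CPM and Wt1 at 100.3 ± 37.6 and 97.4 ± 31.2 CPM. That list did not pass without control 2 (0.0912) or without the library labelled Htr2b_cKO 4 (0.052), or with sex as a covariate (0.0546).

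Macrophage transcripts varied within groups. They made up 0.338% and 0.113% of counts in the control libraries and 0.11%, 0.281%, 0.532% and 0.0606% in the Htr2b_cKO libraries, and the list did not pass (9 of 19 above 0, camera adjusted p = 0.559). It passed on the higher side without control 1 (0.0294) and on the lower side without control 2 (0.00641) or the library labelled Htr2b_cKO 3 (0.0147). Lyz2 had 849 ± 677 CPM in control and 1049 ± 1071 CPM in Htr2b_cKO libraries, and Cd14 had 262 ± 64 and 213 ± 75 CPM. Cardiomyocyte markers did not pass (14 of 18 below 0, camera adjusted p = 0.107), but passed lower without control 2 (3.12e-05), Htr2b_cKO 1 (0.0346) or the library labelled Htr2b_cKO 3 (0.0158), with Myh6 at 6.78 ± 5.65 and 5.86 ± 3.97 CPM and Tnnt2 at 7.00 ± 5.85 and 5.43 ± 3.31 CPM. Mural markers did not pass (8 of 11 below 0, camera adjusted p = 0.156), but passed lower without control 2 (3.91e-05). Pdgfrb had 233 ± 5 and 219 ± 56 CPM and Ndufa4l2 49.99 ± 20.3 and 45.2 ± 12.8 CPM, while Vtn was called over the list alone (adjusted p = 0.0298) at 7.33 ± 0.83 and 2.63 ± 1.00 CPM. Schwann cell markers did not pass camera (3 of 5 tested above 0, adjusted p = 0.909) and did pass the mixed test of fry (adjusted p = 0.0119). Mbp had 32.3 ± 2.4 and 22.8 ± 2.7 CPM and Ngfr 16.6 ± 0.8 and 7.84 ± 4.87 CPM. The Schwann median was positive (0.41) while camera's direction was down. Erythroid markers did not pass (5 of 5 tested below 0, camera adjusted p = 0.107), but passed lower without control 2 (0.000411) or Htr2b_cKO 1 (0.0186), with Hbb-bs at 14.3 ± 11.9 and 7.13 ± 5.53 CPM and Hba-a1 at 8.69 ± 7.84 and 5.39 ± 2.62 CPM. Of the adipocyte list 1 gene passed the filter, Cfd, at 0.026 ± 0.037 and 0.418 ± 0.51 CPM, and the list was not tested.

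**Figure D4:**
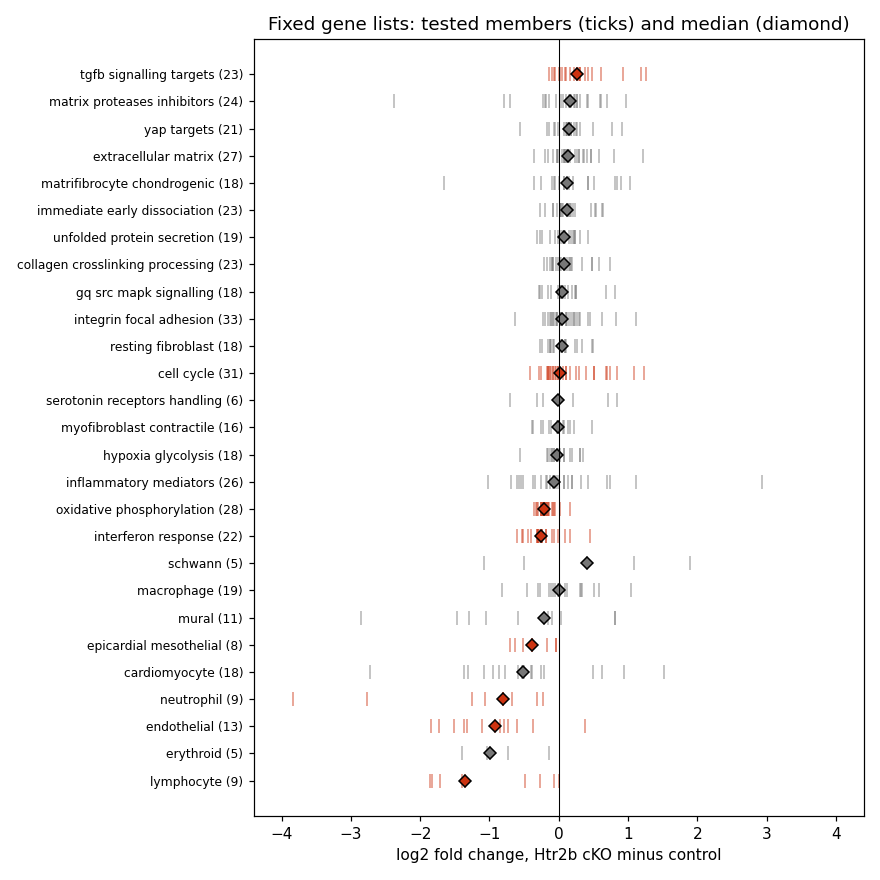
Log2 fold change, Htr2b cKO minus control, of each tested member (ticks) of the 27 lists, with the list median as a diamond and the number of tested members in brackets. Lists with a camera adjusted p under 0.05 are red and the others grey; medians ran from -1.35 for lymphocyte markers to 0.41 for Schwann cell markers, and without control 1 the endothelial median turned positive (0.48) and the lymphocyte median was -0.13.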

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

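Tests of the ratio of Jchain to Ighm, of sex and of genotype for the immunoglobulin pattern were chosen only after the values were seen, as were those of the copies, of the summed family and of the region around Postn, and the comparison of control 2 in GC. The test of the GC and length trends, the one without control 1, the correlation of B-cell and plasma-cell markers with Ighm and the comparison of other splits were set before the values they measure were seen. Of 82 values examined for a library far from the others within the Htr2b_cKO group, 13 stood apart. The cutoff gives about 1 in 20 for independent, normally distributed values. CPM values are skewed, and pairs such as Kdm5d and the Y-linked sum, or S100a8 and S100a9, are not independent. The 13 can therefore not be read as an excess.

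Htr2b was at 0.876 CPM in the library labelled Htr2b_cKO 3, and the other Htr2b_cKO libraries had 0 to 0.119 CPM. Tnnt2 was at 10.4 CPM in the library labelled Htr2b_cKO 3 and at 3.49 to 4.13 CPM in the others. In the library labelled Htr2b_cKO 4, Maoa was at 24.1 CPM (others 16.9 to 17.8), Ndufa4l2 at 64.3 CPM (others 36.5 to 40.6), S100a9 at 42.2 CPM (others 11.7 to 12.3) and S100a8 at 23.4 CPM (others 4.88 to 7.37). Kdm5d was at 26.6 CPM and the Y-linked sum at 139 CPM in this library, which came from a male. Immunoglobulin segments stood apart because the other libraries of the group had 0 counts: Ighv4-1 at 0.151 CPM and Ighv1-80 at 0.242 CPM in the library labelled Htr2b_cKO 3, and Ighv2-9-1 and Igkv12-41 at 0.119 CPM each in the library labelled Htr2b_cKO 4. Ighm was at 879 CPM in the library labelled Htr2b_cKO 4 and at 139 to 263 CPM in the others.

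Rps3a3 and Rps3a2 were higher and Rps3a1 lower in Htr2b_cKO. The log2 ratio of the summed family, -0.05 against a within-group SD of 0.15, is what reads of one gene divided differently among its copies would give (value -0.0504). A sequence variant of Rps3a1 on a chromosome 3 haplotype carried with the Cre allele is a candidate explanation, because Rps3a1 and Tpm3 both lie on the chromosome of Postn, and a variant may send reads to a copy. Other copies whose parents lie within 50 Mb of Postn had an unadjusted p under 0.05 in 3 of 16 cases. Elsewhere 30 of 604 did (one-sided Fisher exact p = 0.0479). The haplotype stays open, since only 3 copies, Hist1h2al, Gm13337 and Gm14038, carry the result and the first had been seen beforehand. The rule as written, a Fisher exact p under 0.05, was met. It was changed after the value was seen to need more copies than these 16. The allele and the genotype cannot be told apart in this design.

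Most genes with a low unadjusted p were higher, and those 311 with p under 0.01 were long, with a median exon length of 7331 against 4156 bases for all tested genes, and low in GC, at 40.4% against 49.8%. The correction for trends of GC content and length between libraries left 89 such genes. It was fitted to these same libraries with the group difference included, so a fall was close to fixed in advance. The fall therefore cannot tell a trend between libraries from an effect of genotype on such genes. Over genes, which are not independent replicates, the Spearman correlation of fold change with GC was -0.53, and -0.325 without control 1, and control 2 (correlation of its level with GC 0.202) also lay apart from the Htr2b_cKO libraries (-0.283 to -0.136), so control 1 did not carry the whole trend; the part it carried stays open. The correction kept all 3 calls and added Tpm3-rs7. A difference in genotype that acts on long, AT-rich genes remains possible and was not tested.

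Immunoglobulin genes were lower in most Htr2b_cKO libraries. Sex was argued against, because the control to Htr2b_cKO ratio of Ighm was 2.9 over all libraries and 5.59 over the 5 females. Genotype alone stays open: the library labelled Htr2b_cKO 4 reached 0.845 of the control mean, but it is 1 library and the only male. The rule as written counted 1 such library against genotype alone, and it was changed after the value was seen to need more than 1. Differing amounts of RNA from plasma cells are a possible explanation: the ratio of Jchain to Ighm spanned 1.36-fold while Ighm spanned 7.49-fold, with Jchain up to 142 CPM, Mzb1 up to 16.7 CPM and Pou2af1 up to 7.81 CPM, although a sort on PDGFRa should remove such cells and how their RNA would remain was not tested; Derl3 and Tnfrsf17 parted the libraries as Ighm did, while Tnfrsf13b did not, at 7.73 CPM in the library labelled Htr2b_cKO 3 against 4.48 and 2.10 CPM in control. The test set beforehand, a correlation of 16 B-cell and plasma-cell markers with Ighm over all libraries, was not computed. The libraries fell into 2 clusters of 3 each, at 139 to 263 and 879 to 1042 CPM of Ighm. That ground for leaving it out was chosen once these values were seen.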

How the results depend on the processing

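The alternatives of GC and length correction, the authors' factors, leaving out both Htr2b_cKO 3 and Htr2b_cKO 4, and the macrophage covariate were chosen after seeing the data. No paired analysis was possible because the labels give the groups no shared replicate numbers. The main count was 3 calls, 2 higher and 1 lower. It was 5 without a filter (2 lower), 105 with DESeq2 (85 higher, 20 lower), 1 with limma voom (1 higher, 0 lower), 8 with sex as a covariate (5 lower), 5 without both Htr2b_cKO 3 and Htr2b_cKO 4 (3 lower), and 9 with the macrophage covariate (5 higher, 4 lower). The legacy dispersion and the authors' factors gave 0 lower. The sex term takes up the only male library, Htr2b_cKO 4, and leaving that library out likewise gave 8 calls (5 lower). These 2 settings are therefore not separate checks. Leaving out each library gave 1 to 8 calls, 1 to 3 higher and 0 to 5 lower, and 541 to 1961 genes with an unadjusted p under 0.05. In 2 of these fits a single control is assumed to vary like the other group. DESeq2 also called 52 unchanged genes in simulated data. The 8 lists became 0 with an estimated correlation and 0 with fry, and 5 to 12 when each library was left out.

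Postn stayed negative throughout (leave-one-out -0.588 to -0.0427). For Htr2b the sign turned with sex as a covariate (0.158) and over the left-out libraries (-1.97 to 0.259). With the GC and length correction the sign turned for Lpl (-0.0684), Pdgfrb (0.00541), Ndufa4l2 (0.168), Wt1 (0.0237) and Xist (-0.158). It turned with limma voom for Lyz2 (-0.111) and Xist (-2.14), with sex as a covariate for Myh6 (0.0327) and Cd4 (0.0655), with the authors' factors for Myh6 (0.631), and without both Htr2b_cKO 3 and Htr2b_cKO 4 for Myh6 (0.00132), Lyz2 (-0.164) and Wt1 (0.106). Leave-one-out ranges that crossed 0 were -0.774 to 0.179 for Acta2, -3.18 to 0.255 for Timp4, -0.907 to 0.0271 for Ankrd37, -0.889 to 1.05 for Myh6, -1.03 to 0.928 for Tnnt2, -1.83 to 0.478 for Pecam1, -0.271 to 0.0400 for Pdgfrb, -0.504 to 0.341 for Ndufa4l2, -0.59 to 1.5 for Lyz2, -1.39 to 0.238 for S100a9, -1.17 to 0.882 for Cd4, -0.383 to 0.408 for Wt1, -1.68 to 0.26 for Hbb-bs, -1.41 to 0.758 for Hba-a1 and -0.0644 to 0.659 for Xist. None of these genes was called. Ranges that kept their sign but moved by over 1.5 times were 0.237 to 0.609 for Lum, 0.439 to 0.879 for Loxl4, 0.128 to 0.606 for P4ha3, 0.264 to 0.745 for Abca8a, 0.278 to 0.815 for Runx2, -0.525 to -0.147 for Cxcl10, 0.273 to 1.32 for Ptgs2, 0.0217 to 0.877 for Tek, -0.873 to -0.126 for Ankrd1, -0.52 to -0.0253 for Cd14 and -2.31 to -0.52 for Cd79a, among others.

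List directions, given as adjusted p, turned for myofibroblast genes with sex (0.789), the GC correction (0.56), without both libraries (0.616), the macrophage covariate (0.928) and fry (0.997), for Schwann markers without a filter (0.888) and with the authors' factors (0.881), for unfolded protein (0.776) and macrophage (0.168) lists with sex, for hypoxia with the GC correction (0.44), without both libraries (0.735) and with fry (0.997), and for resting fibroblast genes without both (0.468). Leave-one-out adjusted p values of lists that turned ran from 0.00245 to 0.984 for myofibroblast (passing in both directions), 0.396 to 0.983 for protease, 0.147 to 0.981 for resting fibroblast, 0.000122 to 0.892 for matrifibrocyte, 0.00245 to 0.994 for inflammatory, 0.00641 to 0.779 for immediate early, 0.205 to 0.994 for hypoxia, 0.0897 to 0.779 for unfolded protein, 3.12e-05 to 0.348 for cardiomyocyte, 4.05e-28 to 0.0204 for endothelial, 3.91e-05 to 0.481 for mural, 0.00641 to 0.994 for macrophage, 3.95e-07 to 0.605 for neutrophil, 0.471 to 0.967 for Schwann and 0.000411 to 0.563 for erythroid. The endothelial median also went both ways, at 0.48 without control 1 and -1.49 without control 2. So did the macrophage median, at 0.99 without control 1 and -0.57 without control 2. Over gene values, 1305 kept direction and side of the threshold, 37 turned direction, 24 gained a call and 11 lost it. A gene called in neither fit counts as kept, so the 1305 say little about stability. Over list values, 423 kept both, 36 turned direction, 26 came to pass and 28 ceased to pass. Except where libraries or genes were removed, the cause was not tested. Low counts limit Htr2b and the immunoglobulin segments.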

Other observations

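The tests of chromosomes and of the region around Postn were chosen only after the values were seen, as was that of the camera p of the cell cycle list; the test of its median was set before its corrected value was seen. Chromosome 3 held more genes with a low p than the other chromosomes. After the GC and length correction, and leaving out Postn, Rps3a1, Tpm3 and near-identical copies, 24 of its 736 tested genes (3.26%) had an unadjusted p under 0.01, against 1.19% over all chromosomes (one-sided Fisher exact, adjusted p = 0.000139 over 20 chromosomes). Lrat, which encodes a retinol-esterifying enzyme, had 0.184 ± 0.149 CPM in control and 1.80 ± 1.01 CPM in Htr2b_cKO libraries. Rbm46, an RNA-binding protein gene, had 0.601 ± 0.224 and 3.49 ± 0.55 CPM, and Glrb, a glycine receptor subunit gene, 0.088 ± 0.022 and 0.936 ± 0.219 CPM. These 3 genes start between 80843599 and 82892579 on chromosome 3, and all 4 Htr2b_cKO libraries lay above both controls for each.

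A haplotype inherited with the Cre allele at Postn, on a mixed 129S2/C57Bl6 background, may contribute to this. Within 40 Mb of Postn 11 of 336 genes had such a p, against 170 of 14878 elsewhere (one-sided Fisher exact p = 0.00232). Within 20 Mb, where linkage would be tightest, only 2 of 120 did (one-sided Fisher exact p = 0.419), and within 30 Mb 9 of 181 did (one-sided Fisher exact p = 0.000318). With 120 genes an excess nearest the allele can be neither shown nor excluded. The 40 Mb result met the rule as written. That rule was changed after the values were seen, to need the 20 Mb window to pass too. Genes on a chromosome are not independent, and 40 Mb was 1 of 7 windows tried, from 10 Mb (one-sided Fisher exact p = 0.525) to 80 Mb (p = 0.000227). Skil, of the TGF-β list, starts at 31095058 and is 1 of the 11 genes, so the same doubt applies to it. The haplotype cannot be told apart from the effect of the genotype, because every Htr2b_cKO animal carries the allele.

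For the cell cycle list, the median moved from 0.02 to 0.11 after the GC and length correction, and the number of its 31 genes above 0 from 16 to 23. The list still passed camera on the higher side (adjusted p = 0.00781 at the preset correlation), while the same correction took the higher genes with unadjusted p under 0.01 from 311 to 89. This argues against those trends as the whole of that camera result only, since before the correction the list did not pass with its estimated correlation of 0.442 (adjusted p = 0.799) or with fry (adjusted p = 0.766).

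Of the 15 splits of the 6 libraries into 2 and 4, 3, the real one included, gave at least as many called genes as the real one, which gave 3. The highest other gave 6. With 15 splits no share can fall under 0.05. The split with 6 calls set control 1 and the library labelled Htr2b_cKO 3 apart from the rest, and it gave 2498 genes with an unadjusted p under 0.05, against 1519 for the real split; the split of Htr2b_cKO 1 and Htr2b_cKO 4 from the rest gave 1622. Control 1 and the library labelled Htr2b_cKO 3 had the highest shares of macrophage transcripts, at 0.338% and 0.532% of counts.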
